A study of Rattus norvegicus with 18 samples.

How the data were processed

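The series concerns the nucleus pulposus (NP), the gel-like core of the intervertebral disc, of rats aged 2, 10 and 20 months. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was purified on oligo(dT) beads and fragmented, and part of the fragments was incubated with an antibody against N6-methyladenosine (m6A). This methyl mark on RNA bases is set by writer proteins, removed by erasers and bound by readers. An immunoprecipitated (IP) library and an input library without immunoprecipitation were made from each sample. The labels list 18 libraries, 9 input and 9 IP, with 3 of each kind per age. The tables used here hold the 9 input libraries, which measure RNA abundance, and the values of the IP libraries are not analysed here, so that no m6A level is reported. The planned comparisons of IP over input and their relation to expression were not run for that reason.

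The deposited gene table gives FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) per gene for each library, per the file headers. The deposited isoform table gives FPKM and read coverage (mean reads per base, not scaled for depth) per transcript, per the file headers. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR without saying what each was used for. The genome build and annotation version are not given in the sources used here, and coordinates are printed as the tables give them, with gene names from the tables. The gene table lists 18923 genes, and 24143 transcripts are in the isoform file. In the values themselves, FPKM divided by coverage was 1 constant per library, and the gene FPKM equalled the isoform FPKM times length, summed and divided by a fixed length per gene. This length varied by under 1% between libraries for 100% of the 11908 genes on which it could be computed. The tables give no counts. The bases behind each library were therefore taken from that constant, which gave 3.53 to 5.04 gigabases per library. The length of a single read was taken from the commonest product of coverage and transcript length between 100 and 200 bases. Fragments per gene were estimated as bases over 2 read lengths for the checks of counting noise.

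Genes with FPKM of at least 1 in at least 3 of the 9 input libraries (11708 genes) were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend) on log2(FPKM + 1), in a single fit over the 9 libraries and the contrasts 10 against 2, 20 against 2 and 20 against 10 months. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold-change minimum, and a moderated F test asked for any difference among the ages. All adjusted p-values in the text come from limma. The 29 gene lists, the design and the rule for named genes were fixed before the data were examined, and 27 lists had enough tested members for limma's set test camera. It was run with its preset inter-gene correlation of 0.01 and again with the correlation estimated from the data. Of 501 list members, 434 were in the table and 277 were tested. Members' calls were also adjusted over the list alone. Pathway terms of the KEGG database were read from the deposited gene table and tested the same way for the 293 terms with 10 to 300 tested genes. These terms were chosen after the data were seen.

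Isoform use was tested with limma on the log2 ratio of an isoform's FPKM to the summed FPKM of the gene's other isoforms, with 0.5 added to both. The genes had at least 2 isoforms and a mean summed FPKM of at least 5, and the isoforms a mean share of 10 to 90%, which left 2771 isoforms of 1328 genes.

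The named genes follow this rule. Per comparison they are the 4 rising and 4 falling genes with the largest change among called genes whose groups do not overlap, whose mean FPKM is at least 5 in the higher group and whose symbol is not a placeholder. To these come up to 3 called members of each main list and up to 2 of each other list with the smallest adjusted p, and Mettl3, Mettl14, Wtap, Fto and Alkbh5 whether called or not. A list with no called member is represented by its highest member, as values only. For isoforms they are the 3 called per direction with the smallest adjusted p. Less telling list members were left out, as the rule allows. Other genes that are named to spell out a short list of calls were chosen after their values were seen, which are Cdh6, Loxl1, Hbb, Hbb-bs, Ythdf2, Elavl1, Vegfa, Lmnb1, Hmgb1, Col3a1, Atf3, Junb and Insig1 in the report. Genes that share sequence with close copies, such as the hemoglobin genes, ribosomal protein genes and small RNAs, are uncertain wherever the quantification could split their reads, and antisense partners cannot be told apart, since strandedness is not given in the sources used here.

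Alternatives were other pseudocounts (0.1 and 5), other filters, rescaling to a fixed sum, quantile normalization, median-of-ratios scaling, fits on only the ages compared, limma without trend, with the robust option or with array weights, the replicate number as a block, a log2 change of at least 1, and leaving out each library in turn. After the data were seen, limma's voom on the estimated fragments and scaling without ribosomal protein and mitochondrial genes were added. On simulated data with 200 genes changed by a log2 value of 0.5, the test recovered 99.0% of them for 10 against 2 months, 98.5% for 20 against 2 and 97.0% for 20 against 10, with 0%, 7.08% and 8.92% of the calls false. The isoform test recovered 19.0% of 200 isoforms changed by a log2 ratio of 1 and 68.5% of those changed by 2, with 9.5% and 6.2% of the calls false. The simulated genes had spreads smoothed over genes of similar level and no shift between libraries. Far more genes were called in the real libraries, so the simulated rates need not hold there. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.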

Results

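The data were the input RNA profiles of 9 libraries of rat nucleus pulposus, 3 each at 2, 10 and 20 months of age. Judged from the ratio of FPKM to coverage, the libraries held 4.77 to 5.04 gigabases of alignments at 2 months, 4.35 to 4.74 at 10 months and 3.53 to 4.90 at 20 months. Between 11027 and 11447 genes per library had an FPKM of at least 1. The keratin gene Krt19, a marker of notochord-derived NP cells, stood at 5268 ± 193 FPKM (SD, n = 3) at 2 months. The labels do not say whether the 3 replicates of an age came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Replicates of 1 age correlated across genes with Pearson's r of 0.984 to 0.993 on log2 values. The median per-gene chi-square between replicates was 0.551 to 0.662 at 2 and 10 months and 1.29 to 1.49 at 20 months, where counting noise alone gives 0.455.

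The 20-month libraries also stood apart in ways that do not belong to single genes. Their read length peaked at 141 bases and that of all 2- and 10-month libraries at 132 bases. On listed transcripts lay 80.1 to 80.9% of their bases, against 85.6 to 86.1% in the other libraries. Ribosomal protein genes held 14.2 ± 0.191% of the summed FPKM at 2 months, 16.5 ± 0.132% at 10 months and 20.7 ± 0.294% at 20 months (SD, n = 3 each), while mitochondrial genes held 0.527 ± 0.061%, 0.619 ± 0.0652% and 0.0984 ± 0.0122%. No 20-month library shared the read length of the other ages. The labels name no batch. Whatever set these libraries apart is called the batch below and cannot be told from age in either comparison with 20 months. The log2 changes of 10 against 2 months are free of this batch, while their p-values rest on a spread shared with the 20-month libraries. Any difference in handling between the 2- and 10-month libraries cannot be told from age either. The 2 ages shared a read length but also differed in the share of ribosomal protein genes.

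**Figure D1:**
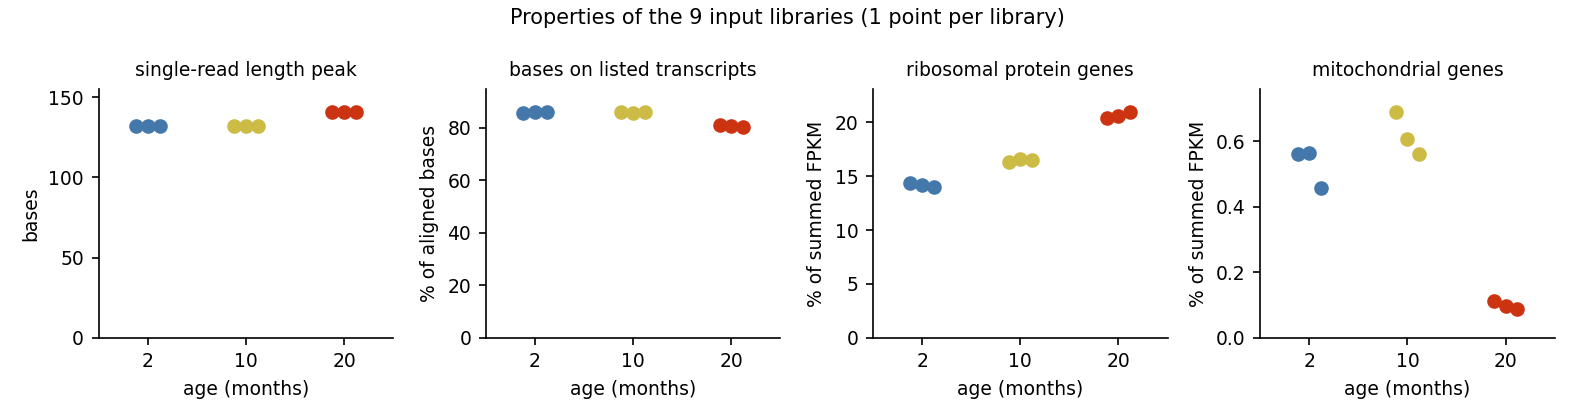
Properties of the 9 input libraries by age in months, with 1 point per library: peak of the read length in bases, percent of aligned bases on listed transcripts, and percent of the summed FPKM in ribosomal protein and in mitochondrial genes. The 20-month libraries peak at 141 bases against 132 and hold 0.0868 to 0.111% of FPKM in mitochondrial genes against 0.456 to 0.690%.

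Between 2 and 10 months, from young to mature adult rats, several genes of the disc matrix fell. Col2a1, which encodes the main collagen of cartilage-type matrix, fell from 304 ± 6.41 to 113 ± 2.61 FPKM (log2 fold change −1.42 ± 0.09 SE, adjusted p = 2.52e-05). The small proteoglycan gene Fmod fell from 784 ± 18.7 to 509 ± 9.98 FPKM. Sparc, which encodes a collagen-binding matrix protein, fell from 1006 ± 9.05 to 668 ± 22.8 FPKM. Among the genes with the largest rise was Cytl1, which encodes a secreted cytokine-like protein made in cartilage, and which went from 3.36 ± 0.0484 to 17.6 ± 1.21 FPKM (log2 2.09 ± 0.13, adjusted p = 2.3e-05). Ppp1r1b, which encodes a phosphatase regulator, rose from 2.75 ± 0.221 to 20.4 ± 0.773 FPKM (2.52 ± 0.11, adjusted p = 3.36e-06). The largest falls were those of the hemoglobin genes Hba-a1, from 51.5 ± 3.50 to 5.88 ± 0.742 FPKM (−2.93 ± 0.08, adjusted p = 8.26e-07), and Hba-a2. The metabolic kinase gene Pdk4 rose from 1.69 ± 0.06 to 8.91 ± 0.204 FPKM and the small proteoglycan gene Dcn from 2.02 ± 0.422 to 9.83 ± 0.344 FPKM (adjusted p = 0.0148, and 0.051 without 2-month replicate 2). The basement membrane collagen gene Col15a1 fell from 12.7 ± 1.36 to 1.81 ± 0.347 FPKM.

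The cartilage-type matrix list had 13 tested members, of which 0 rose and 6 fell (1 and 9 adjusted over the list alone), with Col11a1 at 23.1 ± 0.124 and 16.7 ± 0.406 FPKM as another example. Limma's camera placed this list below other genes at adjusted p = 3.97e-04, and at adjusted p = 0.0605 with an estimated correlation. Of 14 tested NP and notochordal markers, 9 fell and 2 rose, the same counts adjusted over the list alone (camera adjusted p = 3.97e-04, and adjusted p = 0.0605 with an estimated correlation). Krt19 fell to 3728 ± 47.1 FPKM and Lgals3, which encodes the galactose-binding protein galectin-3, from 2687 ± 25.0 to 1786 ± 3.65 FPKM, while Cytl1 and the cadherin gene Cdh6 (log2 0.95) rose. In the fibrous matrix list 7 of 13 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 4.7e-04, and adjusted p = 0.265 with an estimated correlation). Col1a1, the type I collagen gene, fell from 9.47 ± 0.141 to 0.966 ± 0.0654 FPKM and the type VI collagen gene Col6a1 from 539 to 379 FPKM. Those that rose were Tagln, which encodes an actin-binding protein, from 416 ± 9.49 to 813 ± 36.4 FPKM (log2 0.97 ± 0.04, adjusted p = 3.36e-06), and the collagen crosslinking gene Loxl1 (log2 0.55). Of 10 matrix-degrading enzymes and inhibitors 5 fell and 0 rose, also adjusted over the list alone, among them Mmp14, from 28.6 ± 0.740 to 22.8 ± 0.633 FPKM (camera adjusted p = 0.0132, and adjusted p = 0.122 with an estimated correlation).

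Genes of lipid and cholesterol synthesis fell in 11 of 18 tested members with 0 rising, also adjusted over the list alone (camera adjusted p = 1.2e-06, and adjusted p = 0.0605 with an estimated correlation). Cyp51 and Sqle, which encode enzymes of sterol synthesis, went from 25.2 ± 1.06 to 13.3 ± 0.813 and from 26.0 ± 0.869 to 16.6 ± 0.332 FPKM. In the glycolysis and hypoxia list 11 of 21 fell and 1 rose (13 and 1 adjusted over the list alone), with the lactate dehydrogenase gene Ldha falling from 1173 ± 15.7 to 945 ± 5.49 FPKM and the glucose transporter gene Slc2a1 from 1641 ± 49.8 to 1327 ± 50.6 FPKM (camera adjusted p = 2.03e-04, and adjusted p = 0.152 with an estimated correlation). The immediate early and heat shock list had 3 of 15 falling, also adjusted over the list alone, all chaperone genes, such as Hspa1b, from 98.7 ± 8.36 to 34.1 ± 1.08 FPKM, and Hspb1, from 400 ± 10.0 to 282 ± 1.94 FPKM (camera adjusted p = 0.00183, and adjusted p = 0.265 with an estimated correlation). In the autophagy and lysosome list 7 of 19 fell and 1 rose (7 and 3 adjusted over the list alone), the riser being Gabarapl1, from 69.4 ± 1.88 to 87.9 ± 2.44 FPKM. Its camera adjusted p was 0.0247, against 0.0505 without 10-month replicate 2 and an adjusted p = 0.339 with an estimated correlation. Of 11 interferon and antigen presentation genes 4 rose and 2 fell (4 and 3 adjusted over the list alone), led by the immunoproteasome gene Psmb8, from 1.37 ± 0.0894 to 4.11 ± 0.234 FPKM. Oxidative phosphorylation genes went both ways (2 of 20 up, 3 down, and 1 and 6 after median-of-ratios scaling), as did those of the unfolded protein response (3 of 18 up, 5 down), both also adjusted over the list alone. In the senescence list the chemokine gene Ccl7 fell among 11 (adjusted p = 0.0498 and 0.0612 after median-of-ratios scaling, 0 genes adjusted over the list alone). The call of Ccl7 was lost without 10-month replicates 1, 2 or 3 or 20-month replicate 2 (adjusted p = 0.0906, 0.112, 0.126 and 0.0597). The cell cycle inhibitor gene Cdkn1a stood at 6.24 ± 0.543 and 7.20 ± 0.797 FPKM (adjusted p = 0.456).

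Among markers of other cell types, 4 of 5 tested red blood cell genes fell (Hba-a1, Hba-a2, Hbb and Hbb-bs) and the transferrin receptor gene Tfrc rose, the same adjusted over the list alone (camera adjusted p = 0.00146, and adjusted p = 0.0709 with an estimated correlation). The macrophage receptor gene Csf1r rose from 7.04 ± 0.156 to 12.0 ± 0.141 FPKM as the sole call of 5 in its list, and of 3 endothelial and pericyte genes Pdgfrb rose while Cspg4 fell from 23.3 ± 0.138 to 12.9 ± 0.206 FPKM, all 3 also adjusted over the list alone. Of 11 skeletal muscle markers 0 passed (0 adjusted over the list alone), with Acta1 at 8.99 ± 0.993 and 4.95 ± 0.574 FPKM (adjusted p = 0.681). The spread of this gene came from a single 20-month library, without which its adjusted p for 10 against 2 months was 0.00914 at the same log2 change of −0.75 and the adjusted p of the list was 0.00362. With all libraries the list had an adjusted p = 0.82 with an estimated correlation.

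In all, 3551 of 11708 genes differed between 10 and 2 months by limma at adjusted p under 0.05, 2219 up and 1332 down. With only these 2 ages fitted 4783 were called, and with array weights 5116. By at least 2-fold 33 rose and 38 fell, against 114 and 85 with a pseudocount of 0.1, 8 and 14 with 5, and 131 and 103 with voom. Rising genes made up 62.5% of the calls as deposited, 51.0% after median-of-ratios scaling (1774 up, 1703 down) and 50.5% after quantile normalization. The libraries of the 2 ages did not overlap for 53.8% of genes, against 10% by chance.

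**Figure D2:**
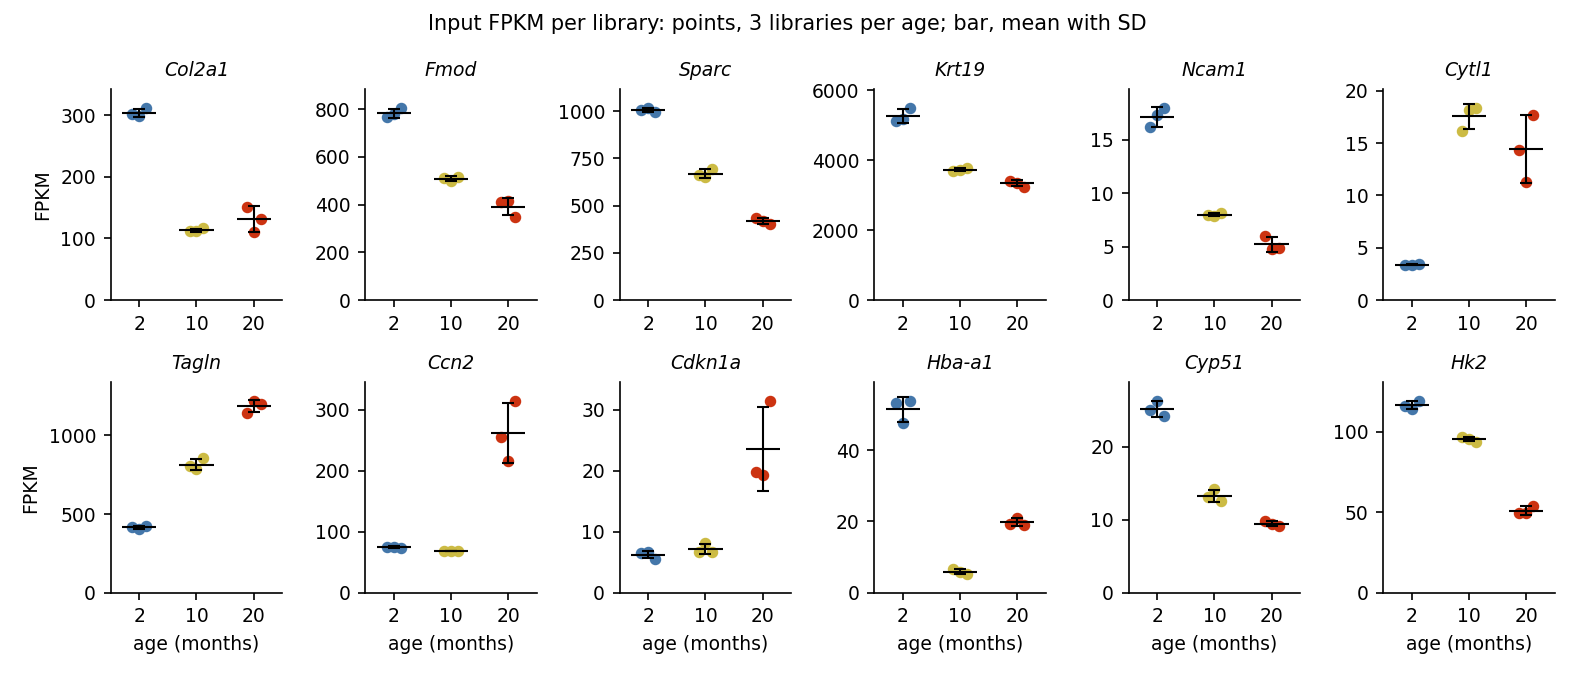
FPKM of 12 named genes at 2, 10 and 20 months, with 1 point per input library, and the mean and SD of 3 libraries as lines. Col2a1 lies at 299 to 311 FPKM at 2 months and at 111 to 152 FPKM in the 6 older libraries, and Ccn2 at 68.3 to 75.8 FPKM except at 20 months, where it lies at 216 to 314.

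Between 2 and 20 months, the span from young to old rats, several genes of the disc matrix were again lower and 3 genes of actin-binding or matricellular proteins were higher. Tagln rose from 416 ± 9.49 to 1187 ± 38.7 FPKM (log2 1.51 ± 0.04, adjusted p = 2.27e-08). Ccn2, which encodes the matricellular protein connective tissue growth factor, rose from 74.7 ± 1.28 to 262 ± 49.2 FPKM (1.78 ± 0.11, adjusted p = 1.21e-06). Nexn, which encodes the actin-binding protein nexilin, rose from 4.37 ± 0.229 to 37.4 ± 4.07 FPKM (2.83 ± 0.08, adjusted p = 3.88e-08). Sparc fell from 1006 ± 9.05 to 418 ± 17.2 FPKM (−1.27 ± 0.04, adjusted p = 3.84e-08). The adhesion gene Ncam1 fell from 17.1 ± 0.913 to 5.21 ± 0.698 FPKM (−1.55 ± 0.08, adjusted p = 4.73e-07), and Col2a1 to 131 ± 20.4 FPKM (−1.21 ± 0.09). The cell cycle inhibitor gene Cdkn1a, also a marker of senescent cells, rose from 6.24 ± 0.543 to 23.5 ± 6.88 FPKM (1.72 ± 0.17, adjusted p = 1.96e-05). The mitochondrially encoded Mt-co1, a subunit of cytochrome c oxidase, showed the largest fall among the genes that meet the naming rule, from 540 ± 39.2 to 52.9 ± 5.49 FPKM (−3.33 ± 0.09, adjusted p = 1.85e-08).

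More genes fell than rose in FPKM at 20 months. Of 7986 called genes 2175 rose and 5811 fell, and 328 and 375 did so by at least 2-fold (513 and 225 after median-of-ratios scaling). The 2-fold counts were 473 and 816 with a pseudocount of 0.1, 146 and 116 with 5, and 605 and 673 with voom. Rising genes made up 27.2% of calls as deposited, 48.6% after median-of-ratios scaling (3560 up, 3765 down) and 44.8% after quantile normalization. Median-of-ratios scaling moved the median gene by 0.20 (log2) in this comparison and by 0.23 for 20 against 10 months, and some genes by more. A log2 change of about these sizes or smaller may therefore not keep its direction under both scalings. Values after that scaling are given below where they matter. The ages did not overlap for 70.4% of genes, against 10% by chance.

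Of 13 cartilage-type matrix genes 9 fell and 1 rose (7 and 1 after median-of-ratios scaling), with Fmod falling from 784 ± 18.7 to 392 ± 36.8 FPKM and Col11a1 from 23.1 ± 0.124 to 11.3 ± 0.105 FPKM. In the NP and notochordal list 8 of 14 fell and 3 rose (7 and 7 after that scaling), with Krt19 falling to 3336 ± 83.1 FPKM and the carbonic anhydrase gene Ca12 from 10.8 ± 0.292 to 4.07 ± 0.622 FPKM. Of 13 fibrous matrix genes 9 fell and 3 rose (8 and 3), the risers being Tagln, Ccn2 and Loxl1. Of 10 matrix-degrading enzymes and inhibitors 9 fell (8), such as the metalloproteinase inhibitor gene Timp3, from 489 ± 10.2 to 300 ± 14.0 FPKM, and the lysosomal protease gene Ctsb, from 532 ± 5.63 to 342 ± 17.2 FPKM. Lipid and cholesterol synthesis genes fell in 15 of 18 (14) with Insig1 rising, for example Idi1, from 12.5 ± 0.216 to 3.94 ± 0.141 FPKM (−1.46 ± 0.06, adjusted p = 1.44e-07, and −1.27 after scaling). Cyp51 fell to 9.48 ± 0.368 FPKM. In the glycolysis and hypoxia list 16 of 21 fell and 4 rose (10 and 7), with the hexokinase gene Hk2 falling from 116 ± 2.39 to 51.0 ± 2.72 FPKM and the glucose transporter gene Slc2a3 from 57.4 ± 1.06 to 20.5 ± 1.80 FPKM. Unfolded protein response genes fell in 13 of 18 and rose in 1 (9 and 4), led by the chaperone gene Dnajb11, from 24.9 ± 0.373 to 14.0 ± 0.651 FPKM, and autophagy and lysosome genes fell in 14 of 19 and rose in 2 (7 and 4). The counts adjusted over the list alone equalled those over all genes for every list in this paragraph. Camera set only the lipid and cholesterol list apart from other genes (adjusted p = 0.0316, adjusted p = 0.504 with an estimated correlation, and 0.05 without 20-month replicate 2). The list of matrix-degrading enzymes and inhibitors passed after median-of-ratios scaling (adjusted p = 0.0468) and without 20-month replicate 3 (adjusted p = 0.0234). As deposited with all libraries it had an adjusted p = 0.504 with an estimated correlation.

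In the senescence and secretory list 3 of 11 rose and 4 fell. These are the same adjusted over the list alone. The list gave its members no expected direction, so the counts do not measure senescence. Those up included Cdkn1a and the vascular growth factor gene Vegfa, and those down included Igfbp7, from 385 ± 13.0 to 201 ± 30.7 FPKM. Inflammation genes fell in 3 of 5 and rose in 1, also adjusted over the list alone, with Nfkb1 going from 12.2 ± 0.437 to 8.04 ± 0.557 FPKM and its inhibitor gene Nfkbia from 16.0 ± 0.993 to 20.3 ± 2.20 FPKM. Of 11 interferon and antigen presentation genes 6 fell and 3 rose, also adjusted over the list alone, with Psmb8 at 4.53 ± 0.950 FPKM (up) and the antigen presentation gene Cd74 at 0.450 ± 0.218 FPKM (down, log2 −1.40). Oxidative phosphorylation genes encoded in the nucleus went both ways, 5 of 20 up and 7 down, also adjusted over the list alone (10 and 2 after median-of-ratios scaling), Cox4i1 rising from 332 ± 4.73 to 462 ± 33.1 FPKM. In the cell cycle list 1 of 7 rose and the thymidylate synthase gene Tyms fell, also adjusted over the list alone (3 and 1 after that scaling). Among other cell types, Acp5, an osteoclast enzyme gene, fell from 15.2 ± 0.492 to 4.94 ± 0.542 FPKM. The lipoprotein lipase gene Lpl fell from 123 ± 2.67 to 41.8 ± 3.43 FPKM and the parathyroid hormone receptor gene Pth1r from 147 ± 1.40 to 76.0 ± 6.70 FPKM, and Prg4, which encodes lubricin, rose from 0.724 ± 0.113 to 5.06 ± 1.35 FPKM. The annulus and tendon list that holds Prg4 had 2 of 6 up and 2 down, and the adipocyte list that holds Lpl 1 of 2 up and 1 down, both also adjusted over the list alone. Hba-a1 and Hba-a2 fell to 19.8 ± 1.08 and 9.39 ± 1.41 FPKM. Skeletal muscle markers passed in 0 of 11 (0 adjusted over the list alone). Acta1 was at 1.73, 0.760 and 92.5 FPKM in the 3 libraries of 20 months, and without the last it lay below 2 months (−2.18, adjusted p = 2.07e-05), as did the list (adjusted p = 0.0215, but with all libraries adjusted p = 0.835 with an estimated correlation). Dcn, a proteoglycan gene among the largest rises (3.19, adjusted p = 2.2e-04), was also uneven, at 13.8, 19.7 and 66.4 FPKM against 2.02 ± 0.422 FPKM at 2 months. A Rpl7a copy rose from 39.4 ± 27.1 to 292 ± 39.5 FPKM, with another copy of that name in the table. The signal recognition particle RNA gene Rn7sl1 fell from 48.3 ± 18.2 to 4.89 ± 0.709 FPKM, and Mt-atp8, a subunit of ATP synthase, from 436 ± 71.7 to 49.4 ± 8.01 FPKM. Of the loci named only by a clone identifier, AC135409 (17.0, 0 and 18.3 FPKM at 2 months, 58.7 to 70.9 at 20) and AC135443 (6.82 ± 2.37 and 0.0335 ± 0.0059 FPKM) also met the rule.

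**Figure D3:**
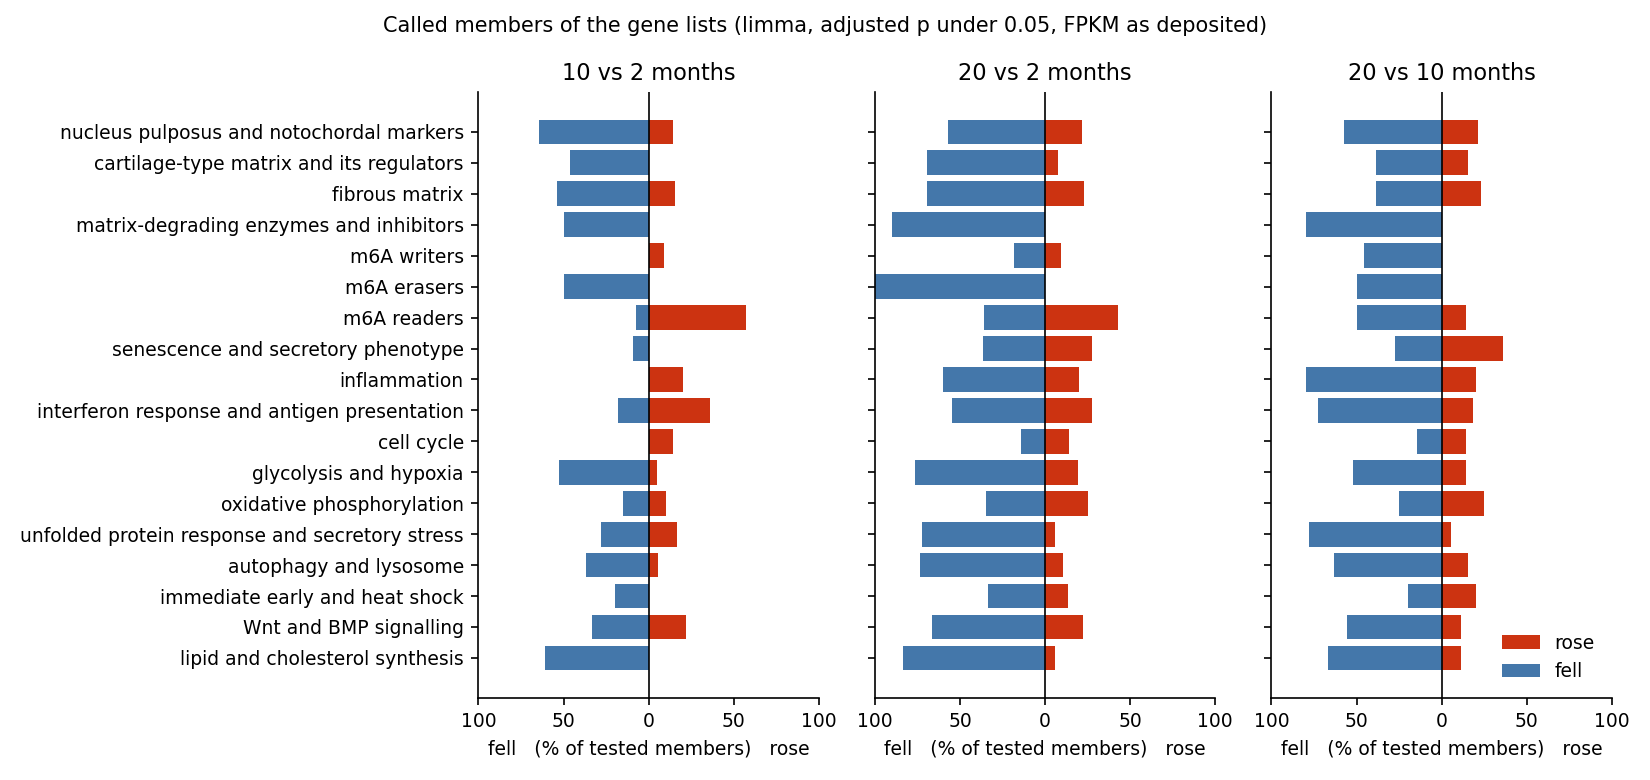
Percent of the tested members of 18 gene lists that rose (right) or fell (left) by limma at adjusted p under 0.05, FPKM as deposited, for the 3 comparisons of ages. After median-of-ratios scaling 10 in place of 16 glycolysis and hypoxia genes fall for 20 against 2 months.

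Between 10 and 20 months, the step from mature to old rats, Ccn2 rose from 68.8 ± 0.458 to 262 ± 49.2 FPKM (adjusted p = 2.17e-06, with a log2 change of 2.15 after median-of-ratios scaling) and Cdkn1a from 7.20 ± 0.797 to 23.5 ± 6.88 FPKM (1.55 ± 0.17, adjusted p = 5.57e-05). Id1, a target gene of bone morphogenetic protein signalling, rose from 4.94 ± 0.850 to 18.9 ± 4.32 FPKM (1.74 ± 0.15, adjusted p = 1.89e-05). Zfp36, which encodes a protein that destabilizes messenger RNA, rose from 15.6 ± 1.09 to 60.7 ± 21.4 FPKM. The keratin genes Krt18 and Krt8 rose from 886 ± 8.14 to 1625 ± 121 and from 3246 ± 23.9 to 4444 ± 117 FPKM, and both also rose after median-of-ratios scaling. Slc2a3 fell from 53.6 ± 1.46 to 20.5 ± 1.80 FPKM (−1.34 ± 0.06, adjusted p = 5.52e-07), the secreted Wnt antagonist family gene Dkk3 from 52.7 ± 0.337 to 24.9 ± 2.19 FPKM, and the interferon-induced Mx2 from 3.51 ± 0.069 to 0.265 ± 0.0702 FPKM. Col2a1 stood at 113 ± 2.61 and 131 ± 20.4 FPKM and was not called as deposited, but rose after median-of-ratios scaling (0.46, adjusted p = 0.00213).

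In total 7576 genes were called, 1339 up and 6237 down, with 152 and 190 beyond 2-fold (256 and 108 after median-of-ratios scaling). These 2-fold counts were 224 and 547 with a pseudocount of 0.1, 72 and 60 with 5, and 286 and 453 with voom. Rising genes made up 17.7% of calls as deposited, 49.4% after median-of-ratios scaling (3035 up, 3113 down) and 44.2% after quantile normalization, and the ages did not overlap for 67.9% of genes, against 10% by chance. The NP and notochordal list had 8 of 14 falling and 3 rising (4 and 7 after median-of-ratios scaling). Cartilage-type matrix had 5 of 13 falling and 2 rising (3 and 4), fibrous matrix 5 falling and 3 rising of 13 (1 and 6), and matrix-degrading enzymes and inhibitors 8 of 10 falling (4, with 1 rising). Adjusted over the list alone these counts were the same except for 4 risers in the fibrous matrix list. Risers of the fibrous matrix list included Col3a1, a fibrillar collagen gene, and fallers Sparc, to 418 ± 17.2 FPKM. Lipid and cholesterol synthesis genes fell in 12 of 18 (10 after scaling), also adjusted over the list alone. The senescence list had 4 of 11 rising, with Cdkn1a, Vegfa and Lmnb1 among them, and 3 falling, with Igfbp7 and Hmgb1 among them. Its members were given no expected direction, so these counts do not measure senescence. The interferon and antigen presentation list had 8 of 11 falling (6 after scaling). For both lists the counts were the same adjusted over the list alone. In the immediate early and heat shock list Zfp36, Atf3 and Junb rose among 15 and 3 fell (7 up and 1 down after scaling), also adjusted over the list alone. This list passed camera only without 20-month replicate 1 (adjusted p = 0.0354), oxidative phosphorylation only without 20-month replicate 3 (0.0251) or after median-of-ratios scaling (0.00826), and skeletal muscle only without 20-month replicate 1 (0.014) or 2 (0.0128). With all libraries these 3 lists had an adjusted p = 0.678, 0.654 and 0.786 with an estimated correlation. Of 5 red blood cell genes 4 rose, with Hba-a1 going from 5.88 ± 0.742 to 19.8 ± 1.08 FPKM, and Tfrc fell, also adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.203 after median-of-ratios scaling and adjusted p = 0.327 with an estimated correlation). Of the largest changes, AC135409 was listed at 0 in all 10-month libraries. The uneven Rpl7a copy lay at 8.80, 13.3 and 139 FPKM at 10 months. AC103024 and the zinc finger gene Zfp600 rose from under 1 to 9.14 ± 1.66 and 7.27 ± 0.391 FPKM. Rn7sl1, Mt-atp8 and AC135443 fell, as did a Metazoa_SRP gene for another copy of the signal recognition particle RNA, at 10.6 to 20.1 FPKM at 10 months and at 0.133, 0 and 0 at 20.

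Over the 3 ages together, 8829 of 11708 genes differed by limma's moderated F test. Genes that fell by 10 months mostly also fell at 20 months, while as deposited this held less often for genes that rose. Of 3551 genes called for 10 against 2 months, 68.7% were called the same way for 20 against 2. These were 1219 of 2219 rises and 1222 of 1332 falls, and 403 genes were called the opposite way. After median-of-ratios scaling they were 1384 of 1774 rises and 1318 of 1703 falls, with 192 opposite calls. Both comparisons share the 2-month libraries. Independent lists of these sizes would give 412 up and 661 down. Pearson's r of the log2 changes across genes was 0.561, against 0.498 for simulated unchanged groups, and the covariance was 0.0876 against 0.0085, a difference of 0.0792. The simulation gave each gene the same spread at all ages, while replicates differed more at 20 months than at 2 and 10 months. Its values for unchanged groups are therefore only approximate. Genes are not independent replicates, and part of the excess may come from the shared libraries.

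**Figure D4:**
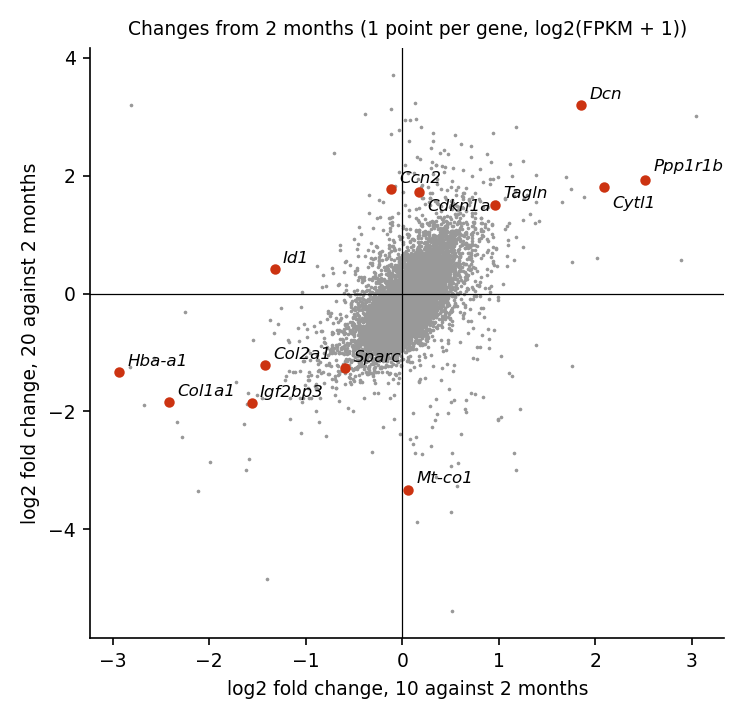
Log2 fold change of FPKM + 1 at 20 against 2 months (vertical) and at 10 against 2 months (horizontal), with 1 grey point per tested gene and 13 named genes in red. Cytl1, Ppp1r1b and Tagln lie up in both, Col2a1, Sparc and Igf2bp3 lie down in both, and Ccn2, Cdkn1a and Mt-co1 moved only in the comparison with 20 months.

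Since the study asked about m6A, the RNA of its writers, erasers and readers was examined. Mettl3 (chromosome 15, 28710300 to 28721127), the catalytic subunit, stood at 15.7 ± 0.323, 15.3 ± 0.0679 and 12.8 ± 0.490 FPKM at 2, 10 and 20 months, with a log2 change of −0.27 ± 0.04 for 20 against 2 months (adjusted p = 2.89e-04) that was −0.07 after median-of-ratios scaling (adjusted p = 0.178). Its partner Mettl14 (chromosome 2, 227566815 to 227582895) stood at 9.44 ± 0.499, 11.1 ± 0.420 and 9.33 ± 1.17 FPKM, and the scaffold Wtap (chromosome 1, 47942500 to 47967631) at 26.2 ± 0.946, 27.8 ± 0.254 and 26.3 ± 0.809 FPKM. Neither was called for 10 or 20 against 2 months as deposited. After median-of-ratios scaling Wtap rose for 20 against 2 months (0.21, adjusted p = 9.74e-04) and for 20 against 10 months (0.17, adjusted p = 0.00471). Mettl14 passed as a rise for 10 against 2 months without 20-month replicate 2 (adjusted p = 0.0141) and with only these 2 ages fitted (adjusted p = 0.0139). It also passed with array weights (adjusted p = 0.016) and with voom (adjusted p = 0.0499). The fall of Mettl14 for 20 against 10 months (adjusted p = 0.0317) was lost without 10-month replicates 1, 2 or 3 or 20-month replicate 2 (adjusted p = 0.0619, 0.0972, 0.0525 and 0.0634), and after median-of-ratios scaling (adjusted p = 0.995). Virma, another scaffold subunit, fell at 20 months from 8.73 ± 0.150 to 5.04 ± 0.243 FPKM (−0.69 ± 0.05, adjusted p = 3.49e-06, and −0.50 after scaling). The eraser gene Alkbh5 (chromosome 10, 46906115 to 46930579) stood at 25.3 ± 0.610, 26.2 ± 0.914 and 19.4 ± 0.282 FPKM and fell at 20 against 2 months (−0.37 ± 0.04, adjusted p = 3.21e-05, and −0.16 with adjusted p = 0.0069 after scaling). The eraser gene Fto (chromosome 19, 16772744 to 17115113) stood at 27.4 ± 1.13, 24.0 ± 0.786 and 24.5 ± 1.23 FPKM. It was lower at 10 against 2 months (−0.19 ± 0.05, adjusted p = 0.019), a call lost without 2-month replicates 2 or 3 or 10-month replicates 1 or 2 (adjusted p = 0.065, 0.0712, 0.0654 and 0.0702). Its value at 20 against 2 months turned from −0.16 (adjusted p = 0.019) to 0.06 after scaling. That call was also lost without 2-month replicates 2 or 3 or 20-month replicate 1 (adjusted p = 0.0595, 0.0699 and 0.0537).

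Among 14 tested readers, 8 rose and Igf2bp3 fell at 10 against 2 months, also adjusted over the list alone (camera adjusted p = 0.019 toward higher levels, and adjusted p = 0.122 with an estimated correlation). Igf2bp3, which encodes an RNA-binding protein of embryonic tissues, went from 4.40 ± 0.614 to 0.823 ± 0.113 FPKM and to 0.482 ± 0.123 FPKM at 20 months (−1.86 ± 0.11, adjusted p = 1.07e-06). The nuclear reader Ythdc1 rose from 34.6 ± 1.12 to 45.2 ± 1.19 FPKM and Hnrnpa2b1 from 182 ± 7.61 to 232 ± 3.56 FPKM at 10 months. At 20 against 2 months 6 readers rose and 5 fell, also adjusted over the list alone (9 and 3 after median-of-ratios scaling), with Fmr1 rising from 12.3 ± 0.290 to 22.6 ± 1.59 FPKM and Eif3a from 39.9 ± 0.891 to 64.9 ± 4.63 FPKM. The falls of Ythdf2 and Elavl1 did not pass after scaling. Writers gave 1 rise at 10 against 2 months (0 adjusted over the list alone), that of Mettl16, whose adjusted p of 0.0314 was 0.0736 after scaling and 0.0607 to 0.0987 without 2-month replicates 1, 2 or 3 or 10-month replicates 1 or 3. At 20 against 2 months 2 of 11 writers fell and 1 rose, also adjusted over the list alone (1 and 6 after scaling). For 20 against 10 months 5 writers fell and 0 rose, 7 readers fell and 2 rose, and of the 2 erasers Alkbh5 fell, also adjusted over the list alone. After scaling these were 2 and 4 writers, 2 and 6 readers, and 1 eraser each way.

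**Figure D5:**
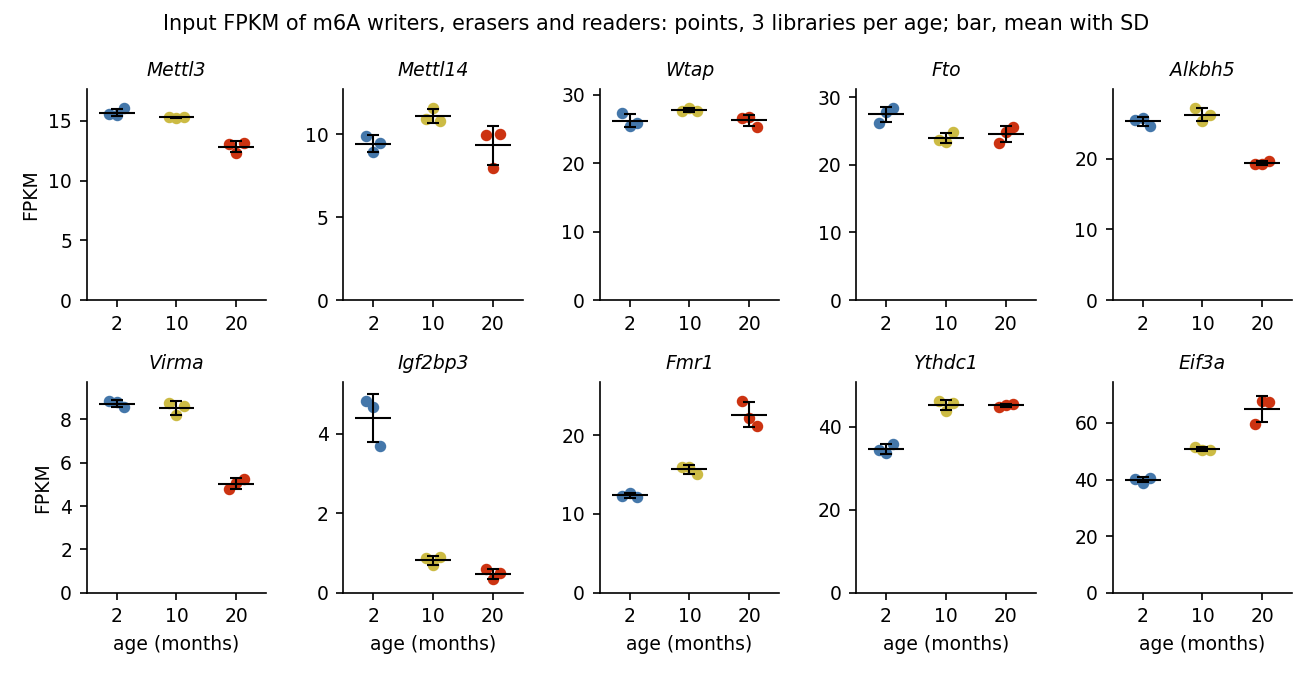
FPKM of 10 genes for m6A writers, erasers and readers at 2, 10 and 20 months, with 1 point per input library, and the mean and SD of 3 libraries as lines. Mettl3 lies at 15.2 to 16.1 FPKM up to 10 months and at 12.3 to 13.1 at 20 months, while Igf2bp3 drops from 3.69 to 4.82 FPKM to under 1.

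Isoform use was compared between 20 and 2 months, to see which transcript of a gene was listed. Fn1, the gene of the matrix protein fibronectin, shifted toward its transcript ENSRNOT00000057585 (chromosome 9, 78900103 to 78969078, 45 exons), whose share of the gene rose from 24.0 ± 0.538 to 50.5 ± 3.10% while it stood at 24.0 ± 1.64% at 10 months (log2 ratio change 1.69 ± 0.14, adjusted p = 0.00213). In Sptan1, which encodes the membrane skeleton protein spectrin, the share of ENSRNOT00000082672 rose from 20.0 ± 4.51 to 59.7 ± 3.34% (adjusted p = 0.00272). In Slfn13, which encodes a protein that cleaves transfer RNA, ENSRNOT00000055963 was listed at 0 in all 2-month libraries, at 37.1 ± 5.51% at 10 months (adjusted p = 0.0166 against 2 months) and at 48.7 ± 15.0% at 20 months (adjusted p = 0.00273). Shares fell for ENSRNOT00000030186 of the RNA granule gene Lsm14a, from 84.5 ± 0.830 to 44.4 ± 4.08% (adjusted p = 4.65e-04). They also fell for ENSRNOT00000087615 of the RNA helicase gene Ddx39b, from 14.1 ± 0.282 to 5.14 ± 0.302%, and for ENSRNOT00000093537 of the ribosomal protein gene Rpl13a, from 39.9 ± 2.73 to 0.863 ± 0.712% (both adjusted p = 0.00116). In all 318 of 2771 isoforms in 170 genes were called, 159 up and 159 down. In a gene with 2 isoforms the 2 ratios mirror each other, so a shift there counts once up and once down. The even balance thus follows in part from the measure, and the count of genes is the better guide. Against this, 7 were called for 10 against 2 months (4 to 11 with a library left out) and 220 for 20 against 10 months. The latter count moved with single libraries left out (75 without 10-month replicate 2 to 190 without 20-month replicate 2). The difference in read length lies between the 20-month libraries and all others. The count of 318 was 101, 114 and 119 without 2-month replicates 1, 2 and 3 and 210 and 205 without 10-month replicates 2 and 3.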

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

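Of the settings reported here, limma's voom on estimated fragments and the scaling without ribosomal protein and mitochondrial genes were chosen only after the data were seen. Other settings for IP over input were not run, since the IP values are not analysed here. The counts of genes called, 3551, 7986 and 7576 for 10 against 2, 20 against 2 and 20 against 10 months, stayed within 1.5 times under every alternative except the minimum log2 change of 1, which left 71, 703 and 342 genes by its own construction. With each library left out in turn they were 2491 to 4065, 7212 to 7922 and 6877 to 7556, and 8256 to 8769 for the F test. The overlap of calls with 2441 in the same direction ran from 1799 to 2694. Without ribosomal protein and mitochondrial genes in the scaling the counts were 3747, 7575 and 7128, and with voom 4007, 7611 and 6973. The share rising stayed below 50% in both comparisons with 20 months under every setting. Median-of-ratios scaling (48.6 and 49.4%) and quantile normalization (44.8 and 44.2%) level the libraries, so these shares are no evidence of more falls. Beyond 2-fold, more genes rose than fell after median-of-ratios scaling, 513 against 225 and 256 against 108. Of 7986 calls for 20 against 2 months, median-of-ratios scaling kept 2175 rises and 3765 falls, lost 2002 falls and turned 44 of the calls, and for 20 against 10 months it lost 3006 and turned 118.

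The replicate numbers did not pair the libraries. Same-numbered libraries of different ages had correlations of deviations from −0.04 to 0.0491 and differently numbered ones from −0.0734 to 0.0628. With the replicate number as a block the counts were 3185, 7859 and 7467, with 122 isoforms in place of 318 at 20 against 2 months and 55 in place of 220 at 20 against 10 months, and the cause was not tested. The isoform count ran from 101 to 265 with a library left out. Gene list calls (12 over the 3 comparisons) became 0 with an estimated correlation and 55 with fry, which asks another question, whether a list moves at all, and were 11 to 16 with a library left out.

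Median-of-ratios scaling turned the direction for Fto at 20 against 2 months (log2 0.0559), and at 20 against 10 months for Mettl3 (0.0044), Mettl14 (7e-04), Wtap (0.1718) and Mbp (0.0479), and quantile normalization did so for Mettl14 (0.0034) and Mbp (0.0055), changes that were about as large as, or smaller than, the shift between scalings. Without 20-month replicate 3, Acta1 turned to −1.4371 at 20 against 10 months (1.43 without 20-month replicate 2) and the skeletal muscle list pointed down at 20 against 2 months (adjusted p = 0.0215, and 0.542 without 2-month replicate 2), since that library alone carried high muscle transcripts. Over all alternatives, values of named genes kept direction and side of the threshold in 4627 of 4884 cases, lost the call in 237 (133 of them under the minimum log2 change of 1) and gained it in 12, and the 6 named isoforms kept both in 72 of 72. No read counts were given, so depth limits were judged from estimated fragments only.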

Other observations

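The terms, the simulated splits of genes and most tests in this part were chosen only after the result was seen, among them the tests of batch, histone genes, small RNAs, oxidative phosphorylation and skeletal muscle. Those of the ribosomal protein share, transcript length, annulus fibroblasts and the splits of the isoform test were written before.

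Many genes of the protein-making machinery were higher at the older ages. Of 162 tested genes of the KEGG term ribosome, 71 rose and 1 fell at 10 against 2 months (median log2 change 0.16), 105 rose and 16 fell at 20 against 2 months (0.50, and 0.72 after median-of-ratios scaling), and 88 rose and 19 fell at 20 against 10 months. Limma's camera placed the term above other genes in all 3 comparisons, and with an estimated correlation at adjusted p = 0.0265 and 0.0142 for 20 against 2 and 20 against 10 months but 0.245 for 10 against 2. It was the only term of 293 with a call under an estimated correlation. In both comparisons with 20 months the batch cannot be told from age for this term. Whether the trend with transcript length described below contributes to it was not tested. Spliceosome genes followed, with 45 of 133 rising and 4 falling at 10 against 2 months and 54 rising and 37 falling at 20 against 2 months (median 0.05, and 0.27 after scaling, with adjusted p = 0.162 under an estimated correlation).

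Genes of the secretory and endolysosomal pathway and of sterol synthesis lay at the other end. Of 14 steroid biosynthesis genes 10 fell at 10 months and 14 at 20 months against 2 months (median −0.94, and −0.74 after scaling). Of 44 genes of N-glycan biosynthesis, the pathway that attaches sugars to secreted proteins, 34 fell and 0 rose at 20 against 2 months (median −0.47, and −0.27 after scaling), and 79 of 104 lysosome genes fell and 9 rose (−0.39 and −0.19). Their adjusted p-values with an estimated correlation were 0.442, 0.369 and 0.369.

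More genes fell than rose at 20 months, with a median log2 change of −0.20 against 2 months. If the larger FPKM share of ribosomal protein genes were the whole cause, the other genes would be level once scaled to a fixed sum among themselves, but their median moved only from −0.201 to −0.121, which argues against it as the whole cause. Transcript length could add to the pattern, since the median was −0.11, −0.21 and −0.25 for the short, middle and long transcripts (median 1000, 2110 and 4023 bases), and the gap of −0.147 between the ends is too small to decide. A library batch stays open as well, because 0 of the 3 libraries of 20 months had the read length of the other ages, and batch and age cannot be told apart. A biological change with age stays open and untested.

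Mitochondrially encoded transcripts were lower at 20 months, with a median log2 change of −1.80 over 19 listed genes. Several of these share the name AY172581 and lack a gene symbol of their own. In all 18 were lower and Mt-nd3 higher, while at 10 months the median was 0.47 against 2 months. A fall of the whole oxidative phosphorylation system is argued against by its nuclear-encoded genes, whose median change was −0.083. Less carry-over of RNA that the oligo(dT) step retains poorly may contribute, and here the values do not decide. The RNAs used for this test are of other kinds, so they cannot show how that step retained mitochondrial transcripts. Replication-dependent histone genes had a median of −0.756 (8 of 9 lower), while 32 genes for small cytoplasmic and nuclear RNAs had a median of −0.277 with 20 lower, and the 7 of them with a mean FPKM of 5 or more a median of −1.96. That subset was set after the median over all 32, most of them near the floor, had been seen. The median over all 32 alone would have argued against carry-over, so the subset is what leaves it open. At 10 against 2 months the histone genes were already lower (median −0.505), so their fall is not particular to 20 months. The 32 small RNA genes were higher there (median 0.446), as were the mitochondrial transcripts. With the batch and the age of the animals these explanations stay open.

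Skeletal muscle transcripts were high in 20-month replicate 3, with Acta1 at 92.5 FPKM against 1.73 and 0.760 in the other 20-month libraries, Ckm at 26.2 against 0.345 and 0.442, and Mylpf at 40.2 against 0.739 and 2.03. All 14 muscle markers in the table (100%) were over 2 times as high there as in both others, so that muscle tissue carried along at dissection may be the source. Annulus and tendon fibroblasts are argued against as the source by their own markers, of which 2 of 11 (18.2%) passed the same bound. Outside that list, and chosen after their values were seen, Col1a1 at 5.09 FPKM against 0.895 and 1.18 and Dcn at 66.4 against 13.8 and 19.7 also passed it, so other connective tissue stays open. The lists were fixed before. Acta1 was at 7.96 to 9.94 FPKM in the 2-month libraries, and whether NP cells express it was not tested. No biological explanation within the design was tested, since the pattern lies in a single library.

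For the F test 100 of the possible splits of the 9 libraries were tried. Only the real one gave a count as large, with 8829 genes against at most 6086 for the others. This argues against chance in how these 9 libraries are labelled. It cannot tell age from the batch of the 20-month libraries. Chance differences between animals are not excluded either, because the replicates may not be separate animals. For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 3551 genes at 10 against 2 months and the highest other 2, 7986 and 2 at 20 against 2 months, 7576 and 1 at 20 against 10 months, and 318 and 4 isoforms at 20 against 2 months, with 1 split of each 10 as large.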
